A study of Mus musculus with 8 samples.

How the data were processed

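Bone marrow cells of 12-week-old mice were depleted of lineage-positive cells with antibodies that included Gr1 and Mac1, stained, and sorted into TRIzol, per the labels' protocols. RNA was purified on columns, and 50 ng per sample was amplified and biotinylated with the NuGEN Ovation Pico WTA kit before hybridisation, per the labels' protocols. Such linear amplification from a small input can exaggerate differences among rare transcripts. The series held 8 arrays, 4 of Chd7 f/f and 4 of Chd7 f/f with Vav1-Cre, and groups and replicate numbers were taken from the sample titles.

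The deposited table holds log2 expression values made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, with no version given. RMA as generally defined corrects background, quantile-normalises all arrays together and summarises the probes of each probe set, so a change that affected most genes alike would be removed. The annotation and genome build behind the probe sets are not given in the sources used here, and no coordinates are printed. The table has 34365 probe sets in 8 columns, and no column belonged to another sample. The platform table listed 25341 of these probe sets: 23521 (68.4%) had 1 gene, 1820 had several and were left unnamed, and 9024 probe sets were not listed. Of several probe sets of a gene (1082 genes), the brightest over all arrays stood for it, which left 22180 genes. Their Entrez identifiers were found in the RefSeq gene table (assembly GRCm38.p6) for 21994 (99.2%), which was used for names only.

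Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over 22180 genes, no filter on dim genes), as Vav1-Cre minus f/f. The moderated variance had a prior of 3.62 degrees of freedom added to 6 residual ones, and the median residual SD was 0.208 log2. All adjusted p-values of genes are from limma. Single values such as Chd7 and list means were also tested by exact permutation over all 70 assignments of the 8 arrays, two-sided, with a smallest p of 0.0286. A background level of 4.95 log2 was set as the 95th percentile of 1394 olfactory and vomeronasal receptor genes, and 12169 genes (54.9%) had a mean above it.

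Gene lists were 29 hand-written lists and 7 lists set by name patterns, of which 1, the mitochondrially encoded genes, had fewer than 3 measured members and was not tested. Of 1026 hand-written entries 944 were measured, 3 of them through another symbol. Camera from limma, with its preset inter-gene correlation of 0.01, tested whether a list moved more than the other genes, with adjustment over the 35 lists. Camera with an estimated correlation and fry were run beside it. Reactome pathways came from the mouse file of fgsea 1.28.0 and were limited to 15 to 500 measured genes. Principal components were computed on the genes centred across arrays.

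The genes named were Chd7, Runx1, Cbfb, Kit, Slamf1, Cd48 and Ly6a in every case, up to 4 members of each list with the smallest p, and the 12 higher and 12 lower genes of largest difference past an adjusted p of 0.05, without overlap between groups and with the higher mean above the median of all named probe sets. Non-coding and receptor-segment symbols were left out of the last part. As no gene passed, that part was filled by the smallest unadjusted p under the same other conditions. Genes named in the text come from these, except Itgam, Ly6g, S100a8, S100a9, Chil3 and Ly6c2, members of the granulocyte list chosen after their values were seen, and Tradd. These rules, the groups, the tests and the lists were fixed before the data were examined.

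The tests were checked on simulated data with the real means and residual SDs of the 22180 genes in 4 against 4 arrays, independent noise, and 50 changed genes of each fold size, drawn from those above background, per simulation over 10 simulations. At an adjusted p under 0.05, 17.8% of 1.5-fold, 64.8% of 2-fold, 93.0% of 4-fold and 97.8% of 8-fold changes were recovered, with 6.2 false calls per simulation. Lists of 30 genes shifted by 0.3 log2 were found in 100% of cases by both versions of camera, and 1% of unshifted lists were called at the preset and 0% with an estimated correlation. The simulated genes were not correlated, unlike real ones, whose estimated correlation reached 0.558 in the granulocyte list. The rates of found lists and of false list calls therefore do not carry over to the real lists. Splits of the real arrays other than the genotypes gave 0 to 18 called lists at the preset.

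Alternatives were a filter on dim genes at the background level or at the median, median centring, a second quantile normalisation, cyclic loess, limma-trend with robust eBayes, array quality weights, averaged probe sets, all rows of the table, the replicate number as a block, other thresholds, each array left out, camera on ranks, pathways of 15 to 200 genes, and other gene choices for the components. Covariates for the Xist level and for the mean of 16 late neutrophil genes were added after seeing the data.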

Results

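The series profiled RNA of long-term haematopoietic stem cells from the bone marrow of 12-week-old C57BL6/J mice. The cells lacked lineage markers, expressed c-kit and Sca1, were negative for CD48 and positive for CD150, the surface pattern used to isolate the most primitive blood-forming cells. One group came from mice homozygous for a floxed Chd7 allele (called f/f below) and the other from mice that also carried the Vav1-Cre driver, which is active in blood cells (called Vav1-Cre). CHD7 is an ATP-dependent chromatin remodeler. Each group held 4 arrays, which the labels call biological replicates without giving the number or the sex of the mice behind each. The 8 arrays had medians of 4.83 to 4.95 on the log2 scale, and their number limits the precision of every comparison. Correlations between arrays ran from 0.95 to 0.985 across probe sets, which are not independent replicates, and Vav1-Cre replicate 3 stood lowest, at 0.95 to 0.968 with the other arrays.

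The floxed gene itself was examined first. Chd7 (Entrez gene 320790) measured 4.49 ± 0.18 log2 (SD, n = 4) in the f/f arrays and 4.49 ± 0.16 (SD, n = 4) in the Vav1-Cre arrays. Single f/f arrays gave 4.68, 4.29, 4.39 and 4.61, and single Vav1-Cre arrays gave 4.65, 4.53, 4.27 and 4.50. The difference was -0.01 log2 (SE 0.13, 95% confidence interval -0.29 to 0.28), with a limma adjusted p of 0.99 and a two-sided exact permutation p of 0.971. Both means lay under 4.95 log2, the 95th percentile of 1394 olfactory and vomeronasal receptor genes that served as a background level. The labels do not say which exons are floxed, and the table holds 1 summary value per probe set. The Chd7 values therefore do not check the genotype labels.

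The comparison of genotypes asked how gene expression of stem cells differed between f/f mice with and without the Vav1-Cre driver. Granulocyte genes stood furthest apart: all 34 measured members of the list had a higher mean in the Vav1-Cre arrays, and the list rose by a median of 1.89 log2, or 3.70-fold (camera adjusted p = 1.21e-28 with its preset correlation, adjusted p = 0.282 with an estimated correlation). Cell cycle genes also rose, with 49 of 60 members higher and a median of 0.22 log2 (adjusted p = 2.88e-10, and adjusted p = 0.268 with an estimated correlation). Genes of stem cell identity fell, with 38 of 44 members lower and a median of -0.18 log2 (adjusted p = 1.23e-06, and adjusted p = 0.426 with an estimated correlation). No single gene passed the gene-wise test. By limma, 0 of 22180 genes had an adjusted p under 0.05 (lowest 0.73), while 1453 had an unadjusted p under 0.05, 686 higher and 767 lower, against 1109 expected by chance.

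Across the 35 gene lists fixed before the data were examined, camera with its preset correlation called 15, of which 11 rose and 4 fell. With a correlation estimated per list, camera called 0 lists (lowest adjusted p 0.268, and 4 at an unadjusted p under 0.05). Among the 15 lists called at the preset, the estimates ran from -0.015 (mast cell, basophil and eosinophil) to 0.558 (granulocyte). Only the mast cell list lay under the preset of 0.01. Where genes of a list correlate more than the preset assumes, the preset p-value is too small. The fry test, which asks whether the genes of a list move on balance in one direction, called 0 (lowest adjusted p 0.146, and 5 at an unadjusted p under 0.05). Exact permutation of the list means gave 0 (lowest adjusted p 0.167, and 6 at an unadjusted p under 0.05), but with 4 against 4 arrays its smallest possible two-sided p is 0.0286, so a list could pass only if most lists reached that value. Of the 35 ways to part the 8 arrays into groups of 4, 6 gave at least 15 lists.

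**Figure D1:**
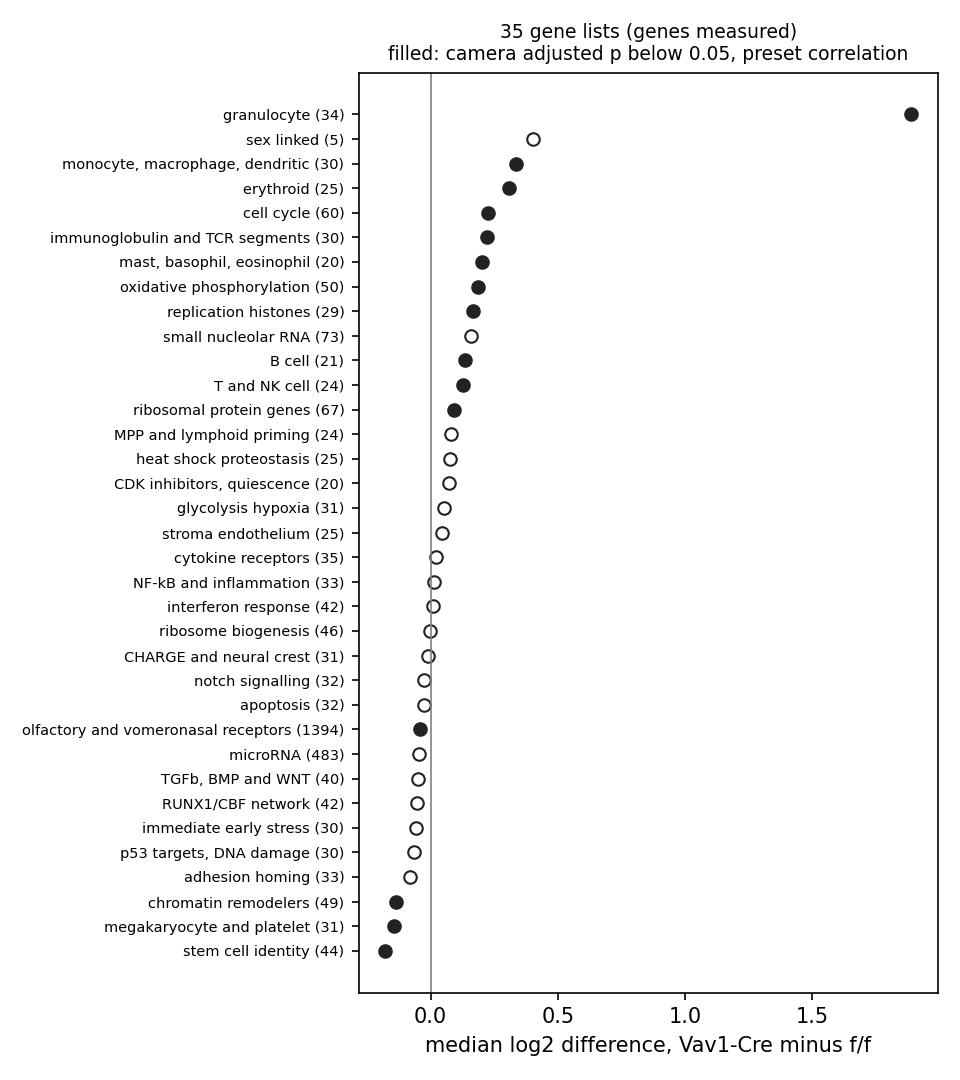
Median log2 difference (x axis, Vav1-Cre minus f/f) of each of the 35 gene lists (y axis, with the number of measured genes), where filled points mark the 15 lists with a camera adjusted p under 0.05 at the preset correlation. The granulocyte list lies at 1.89 log2, apart from all others, and the stem cell identity list lies lowest at -0.18 log2.

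The granulocyte list averaged 6.54 ± 0.90 log2 (SD, n = 4) in f/f arrays and 8.48 ± 0.86 (SD, n = 4) in Vav1-Cre arrays, with a two-sided exact permutation p of 0.0286 and an adjusted p of 0.167 over the lists. In single f/f arrays the list mean was 6.96, 7.59, 5.98 and 5.64, and in single Vav1-Cre arrays it was 8.41, 7.61, 9.66 and 8.26. The separation behind the permutation p was narrow, between 7.59 in f/f replicate 2 and 7.61 in Vav1-Cre replicate 2. Adjusted over the list alone, 28 members passed, all of them higher, against 0 when adjusted over all genes. Camp, Ngp, Ltf and Lcn2, which encode antimicrobial proteins of the secondary granules, differed by 4.67 (SE 1.08), 3.68 (SE 0.74), 3.69 (SE 0.75) and 2.90 (SE 0.67) log2. The primary granule enzymes Elane and Mpo differed less, by 1.92 (SE 0.50) and 1.25 (SE 0.38) log2. S100a8 and S100a9, abundant proteins of the neutrophil cytosol, measured 9.40 ± 2.12 and 8.94 ± 2.14 log2 in f/f arrays and 11.87 and 11.41 in Vav1-Cre arrays, and the S100a9 difference was 2.47 with all arrays and 1.63 without f/f replicate 3. The sort removed cells bearing Gr1 or Mac1, and the genes of these antigens, Ly6g and Itgam, differed by 2.14 (SE 0.86) and 1.39 (SE 0.55) log2, or by 1.18 and 0.81 without Vav1-Cre replicate 3. Chil3 and Ly6c2 have near-identical relatives, so their values are uncertain.

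**Figure D2:**
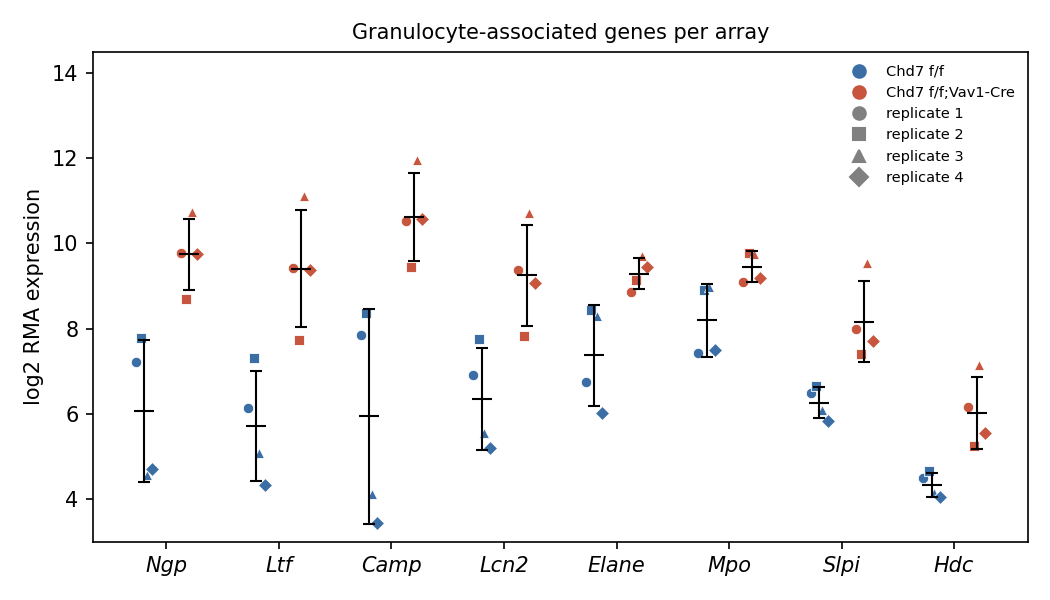
Log2 expression (y axis) of 8 granulocyte-associated genes (x axis) in each array, with f/f in blue, Vav1-Cre in red and the symbol giving the replicate. Black bars give the mean and SD of 4 arrays, Vav1-Cre replicate 3 is the highest point for each gene except Mpo, and Ngp averages 6.07 in f/f and 9.75 in Vav1-Cre arrays.

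Lists of other myeloid cells and of erythroid cells also rose. The list of monocyte, macrophage and dendritic cell genes rose by a median of 0.34 log2 with 25 of 30 members higher (adjusted p = 1.24e-07, and adjusted p = 0.366 with an estimated correlation), and its mean difference was 0.42, or 0.27 without Vav1-Cre replicate 3. Within it, Adgre1, the macrophage antigen F4/80, and the lysosomal glycoprotein gene Cd68 differed by 0.91 (SE 0.25) and 1.01 (SE 0.30) log2. Erythroid genes rose by a median of 0.31 log2 with 20 of 25 higher (adjusted p = 4.07e-05, and adjusted p = 0.513 with an estimated correlation). Their mean difference was 0.41, or 0.21 without Vav1-Cre replicate 3, which stood at 7.52 against 6.38 to 6.96 in the other Vav1-Cre arrays (exact permutation p of 0.143 with all arrays). Slc4a1, the red cell anion exchanger, differed by 1.70 log2 (SE 0.48). The mast cell, basophil and eosinophil list rose by a median of 0.20 log2 with 16 of 20 higher (adjusted p = 0.00233, and adjusted p = 0.268 with an estimated correlation), with a mean difference of 0.59, or 0.38 without Vav1-Cre replicate 3 and 0.91 with only genes above the background level. Adjusted over the list alone, 1 member passed, the histidine decarboxylase gene Hdc, at 4.33 ± 0.29 (SD, n = 4) in f/f arrays against 6.03 ± 0.84 (SD, n = 4). With the mean level of 16 late neutrophil genes as a covariate, a setting chosen after seeing the data, the cell cycle, oxidative phosphorylation, ribosomal protein and olfactory receptor lists still passed, at 0.29, 0.25, 0.20 and -0.09 (0.23, 0.24, 0.11 and -0.04 without it), and the NF-kB, heat shock and ribosome biogenesis lists were gained (mean differences -0.24, 0.25 and 0.16, adjusted p = 0.0180, 0.00314 and 0.00356). The granulocyte list holds these 16 genes, so its loss under that covariate is built in. The covariate itself averaged 6.41 ± 1.41 log2 in f/f arrays and 9.24 ± 1.16 in Vav1-Cre arrays (SD, n = 4 each), so it tracks genotype. A difference made by genotype could therefore also shrink under it, and smaller values cannot be read as due to neutrophils. Of the other lists that no longer passed, mean differences were -0.10 for monocytes, 0.03 for erythroid, 0.36 for mast cell, 0.09 for B cell, -0.07 for T and NK cell, 0.06 for receptor segment, -0.06 for stem cell identity and 0.05 for chromatin genes. Megakaryocyte genes, at -0.24 with it and -0.19 without it, and replication histones, at 0.29 and 0.24, did not shrink.

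Lymphoid lists rose as well. B cell genes, of which 6 were above the background level, rose by a median of 0.14 log2 with 17 of 21 higher (adjusted p = 0.00183, and adjusted p = 0.317 with an estimated correlation), and Jchain, the joining chain of secreted antibodies, differed by 2.69 log2 (SE 0.72). The mean difference of the B cell list was 0.32, and 0.74 and 0.86 with only genes above the background level or above the median. T and NK cell genes rose by a median of 0.13 log2 with 19 of 24 higher (adjusted p = 0.00936, and adjusted p = 0.484 with an estimated correlation), and only Thy1 passed when adjusted over the list alone, at 5.98 ± 0.49 (SD, n = 4) against 7.19 ± 0.27 (SD, n = 4). Immunoglobulin and T cell receptor segments rose by a median of 0.22 log2 with 21 of 30 higher (adjusted p = 0.00569, and adjusted p = 0.484 with an estimated correlation), with a mean difference of 0.54, or 0.33 without Vav1-Cre replicate 3. The name rule for that list also took in Tradd, which is no receptor segment, and its segments have near-identical copies. Ighm belongs to both this list and the B cell list, so their rises are not fully independent. Igkv5-43 averaged 7.53 ± 0.15 (SD, n = 4) in f/f arrays and 9.99 ± 1.55 (SD, n = 4) in Vav1-Cre arrays. The T and NK cell call was lost without Vav1-Cre replicate 3 (mean difference 0.12, adjusted p = 0.0659) and without f/f replicate 3 (0.18, adjusted p = 0.0668), and the segment call without f/f replicate 3 (0.52, adjusted p = 0.0534). With only genes above the background level kept, or only those above the median, the T and NK cell call was also lost, at mean differences of 0.29 and 0.35 (adjusted p = 0.227 and 0.314) against 0.21 with all its genes, and 8 of its 24 genes are above the background level.

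Stem cell identity genes averaged 8.07 ± 0.17 log2 (SD, n = 4) in f/f arrays and 7.84 ± 0.07 (SD, n = 4) in Vav1-Cre arrays, a mean difference of -0.22 with an exact permutation p of 0.114. Jam2, a junctional adhesion molecule, was the 1 member that passed when adjusted over the list alone, at 6.86 ± 0.15 against 6.14 ± 0.25 (SD, n = 4 each). The angiopoietin receptor gene Tek differed by -0.46 log2 (SE 0.15) and Ltb by -0.60 (SE 0.23). Single f/f arrays had list means of 8.21, 7.84, 8.20 and 8.03, and Vav1-Cre arrays had 7.89, 7.87, 7.73 and 7.88. The f/f replicate at 7.84 was also the 1 f/f array with low Xist, at 4.81 log2 against 10.27 to 11.22 in the others. Megakaryocyte and platelet genes fell by a median of 0.14 log2 with 23 of 31 lower (adjusted p = 0.00505, and adjusted p = 0.426 with an estimated correlation). Among them the thrombin receptor gene F2r differed by -0.50 (SE 0.12) and Mmrn1 by -0.70 (SE 0.29), or -0.36 without Vav1-Cre replicate 3. This call was lost without f/f replicate 3 (mean difference -0.16, adjusted p = 0.0981). Mmrn1 and some other members also belong to the stem cell identity list, so the falls of these lists are not independent.

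Chromatin remodeler and modifier genes fell by a median of 0.14 log2 with 37 of 49 lower (adjusted p = 0.00381, and adjusted p = 0.484 with an estimated correlation). The X-linked histone demethylase gene Kdm6a differed by -0.86 log2 (SE 0.24), Ezh1 by -0.36 (SE 0.12) and Paxip1 by 0.74 (SE 0.22). Xist was high in most f/f arrays and in no Vav1-Cre array, so for Kdm6a sex and genotype cannot be told apart. The call was lost without Vav1-Cre replicate 3, where the mean difference was -0.06 (adjusted p = 0.126). The olfactory and vomeronasal receptors, set as a background list, also passed at a median of -0.04 log2 with 883 of 1394 lower (adjusted p = 0.0235, and adjusted p = 0.656 with an estimated correlation). That call was lost without each of f/f replicates 2 and 4 and Vav1-Cre replicates 1 and 2, with mean differences of -0.01, -0.03, -0.03 and -0.03 against -0.04 with all arrays and -0.06 without f/f replicate 3, and when only genes above the background level, 70 of them, or above the median were kept (0.0069 and 0.02), or after a second quantile normalisation or cyclic loess (-0.02 in each).

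Lists of proliferation, respiration and the ribosome itself also rose by camera at its preset correlation, while ribosome biogenesis genes did not pass (adjusted p = 0.884). Cell cycle genes averaged 7.74 ± 0.10 log2 (SD, n = 4) in f/f arrays and 7.97 ± 0.09 (SD, n = 4) in Vav1-Cre arrays, with an exact permutation p of 0.0286 and an adjusted p of 0.167 over the lists. Adjusted over the list alone, 4 members passed: the mitotic kinase gene Aurkb (0.73 log2, SE 0.14), its partner Birc5 (0.72, SE 0.18), Cdca3 (0.52, SE 0.13) and Rrm2, a subunit of ribonucleotide reductase (0.70, SE 0.16). Replication histone genes rose by a median of 0.17 log2 with 18 of 29 higher (adjusted p = 0.00705, and adjusted p = 0.513 with an estimated correlation), a call lost without f/f replicate 1 (mean difference 0.21, adjusted p = 0.130), while the mean difference was 0.24 with all arrays and 0.38 without f/f replicate 3. With only genes above the background level, 17 of the 29, or above the median, it was 0.45 and 0.55. The exact permutation p of the histone list mean was 0.171 with all its genes. Oxidative phosphorylation genes rose by a median of 0.19 log2 with 42 of 50 higher (adjusted p = 5.54e-08, and adjusted p = 0.484 with an estimated correlation). Their largest named difference was 0.80 log2 (SE 0.31) for Atp5d, a subunit of ATP synthase. The exact permutation p of this list mean was 0.171, and f/f replicate 3, at 9.22, lay within the Vav1-Cre range of 9.11 to 9.32. Ribosomal protein genes rose by a median of 0.09 log2 with 49 of 67 higher (adjusted p = 0.00183, and adjusted p = 0.633 with an estimated correlation). That call was lost without f/f replicate 2 (mean difference 0.04, adjusted p = 0.284), after a second quantile normalisation (0.06, adjusted p = 0.0900) and after cyclic loess (0.05, adjusted p = 0.350), against 0.11 with all arrays and 0.17 without f/f replicate 3. The exact permutation p of the ribosomal protein list mean was 0.371, and the Vav1-Cre arrays, at 9.13 to 9.20, lay within the f/f range of 8.87 to 9.26.

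**Figure D3:**
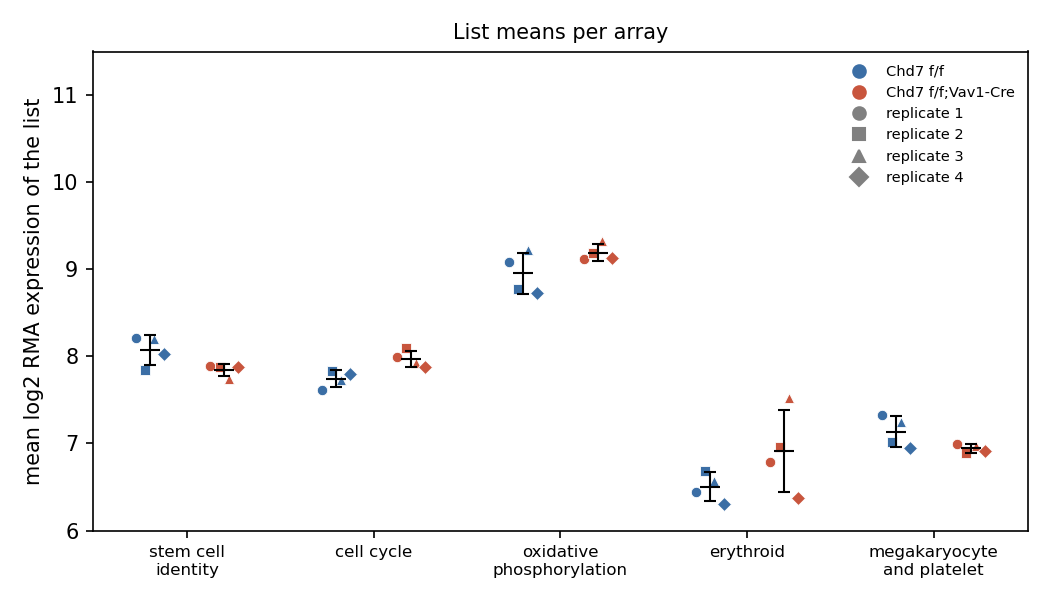
Mean log2 expression (y axis) of 5 gene lists (x axis) in each array, with f/f in blue, Vav1-Cre in red and the symbol giving the replicate. Black bars give the mean and SD of 4 arrays, and cell cycle list means of f/f (7.74 ± 0.10) and Vav1-Cre (7.97 ± 0.09) do not overlap between the groups.

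Among 692 Reactome pathways of 15 to 500 measured genes, camera with its preset correlation called 132, of which 130 rose and 2 fell. DNA strand elongation led (30 genes, 28 higher, median 0.30 log2, adjusted p = 1.93e-07), followed by DNA replication (92 genes, 74 higher, adjusted p = 2.78e-07). The pathways that fell were nuclear signalling by ERBB4 (adjusted p = 0.0456) and signalling by BMP (adjusted p = 0.0478). With an estimated correlation camera called 0 pathways, the lowest adjusted p with an estimated correlation was 0.807, and 30 pathways had an unadjusted p under 0.05 against 180 at the preset. The preset count was 31 without f/f replicate 2 and 65 without f/f replicate 4.

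The other 20 lists did not pass. Multipotent progenitor and lymphoid priming genes had the lowest adjusted p of these, 0.0795 (median 0.08 log2, 17 of 24 higher), and passed without f/f replicate 1 (mean difference 0.29, adjusted p = 0.0247), without f/f replicate 2 (0.29, adjusted p = 0.0388) and without Vav1-Cre replicate 4 (0.30, adjusted p = 0.0186). Within it Ly6d and Cd52 differed by 1.01 (SE 0.33) and 1.48 (SE 0.53) log2, and Ly6d by 0.62 without Vav1-Cre replicate 3. Heat shock and proteostasis genes (median 0.07, adjusted p = 0.129) passed without f/f replicate 3 (mean difference 0.19, adjusted p = 0.00672) and without Vav1-Cre replicate 3 (0.12, adjusted p = 0.0475). Adhesion and homing genes (median -0.08, adjusted p = 0.180) passed without f/f replicate 4 (-0.10, adjusted p = 0.0493) and without Vav1-Cre replicate 3 (-0.10, adjusted p = 0.0408), and with array quality weights over all arrays (-0.10, adjusted p = 0.0259). Of that list, Jam2 and the sphingosine-1-phosphate receptor gene S1pr1, at -0.72 (SE 0.14) and -0.90 log2 (SE 0.18), passed when adjusted over the list alone. MicroRNA genes (median -0.04, adjusted p = 0.141) passed without f/f replicate 3 (-0.07, adjusted p = 0.0465), and immediate early genes (median -0.06, adjusted p = 0.756) without Vav1-Cre replicate 3 (-0.22, adjusted p = 0.0156).

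Signalling and stress lists lay near 0. Medians were -0.05 log2 for TGF-beta, BMP and WNT genes (adjusted p = 0.303), -0.03 for NOTCH genes (adjusted p = 0.756), 0.02 for cytokine receptors (adjusted p = 0.756), 0.01 for interferon response genes (adjusted p = 0.756) and -0.07 for p53 targets (adjusted p = 0.555). The cyclin-dependent kinase inhibitor and quiescence list had a median of 0.07 (adjusted p = 0.555), with the cell cycle inhibitor gene Cdkn1a at a difference of 0.33 (SE 0.10) and Foxo3 at -0.38 (SE 0.13). Glycolysis and hypoxia genes had a median of 0.05 (adjusted p = 0.489), with the glycolytic enzyme gene Pgam1 at 0.59 (SE 0.15) and Egln3 at -0.68 (SE 0.19). Ribosome biogenesis genes were at -0.0038 with 22 higher and 24 lower. CHARGE syndrome and neural crest genes, a theme of CHD7 biology, were at -0.01 (adjusted p = 0.756), and 10 of their 31 measured members were above the background level. Small nucleolar RNAs had a median of 0.16 (adjusted p = 0.570), and Snord88a, at 6.05 ± 0.46 against 4.46 ± 0.39 (SD, n = 4 each), passed when adjusted over the list alone.

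In 5 lists the median, the mean and the camera direction differed in sign. These were the RUNX1 and core binding factor network (median -0.05, mean 0.09, adjusted p = 0.986), stroma and endothelium (median 0.04, mean -0.11, adjusted p = 0.967), NF-kB and inflammation (median 0.01, mean 0.04, camera downward, adjusted p = 0.967), apoptosis (median -0.03, mean 0.02, adjusted p = 0.884) and the sex-linked genes (median 0.40, mean -0.33, adjusted p = 0.756). Without Vav1-Cre replicate 3 their mean differences were, in the same order, 0.07, -0.0002, -0.06, -0.02 and -0.19. Runx1 itself, a master regulator of blood stem cells, differed by -0.07 log2 (SE 0.16) and its partner Cbfb by 0.15 (SE 0.12). Runx1 differed by -0.22 without f/f replicate 2, 0.01 without f/f replicate 3, -0.0057 without f/f replicate 4, -0.02 without Vav1-Cre replicate 3 and -0.11 without Vav1-Cre replicate 4, and Cbfb by 0.07 without Vav1-Cre replicate 4. Members of the RUNX1 network with the smallest p were the granule genes Elane and Mpo, and 4 of its genes were shared with the granulocyte list.

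The 12 higher and 12 lower genes with the smallest p and separated groups all had an adjusted p of 0.73, so none passed. On the higher side they were Palm, Aurkb, Thy1, Ngp, Ltf, Glrx5, Hdc, Foxb2, Slpi, Anxa3, Fabp3 and Bag2, with differences from 0.42 log2 for Foxb2 (SE 0.09) to 3.69 for Ltf (SE 0.75). Thy1, the thymocyte antigen also carried by progenitors, differed by 1.21 (SE 0.24) and the mitochondrial glutaredoxin gene Glrx5 by 0.92 (SE 0.20). Slpi, a protease inhibitor of mature myeloid cells, measured 6.26 ± 0.37 against 8.17 ± 0.95 (SD, n = 4 each). On the lower side they were Zfp266, Zfp747, Cd180, Mtrf1l, Jam2, S1pr1, Nfia, Smg6, Pank1, Ndfip2, Fmnl2 and Rad54l2, with differences from -0.92 log2 for Fmnl2 (SE 0.20) to -0.46 for Smg6 (SE 0.10). S1pr1, whose product guides the egress of blood cells, measured 7.31 ± 0.33 against 6.42 ± 0.24, and the transcription factor gene Nfia measured 7.67 ± 0.12 against 7.13 ± 0.13 (SD, n = 4 each). In all, 863 genes (3.89%) had no overlap between groups, 417 higher and 446 lower, where chance gives 2.86%.

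Among the sort markers, Kit measured 10.37 ± 0.12 in f/f arrays and 10.22 ± 0.14 in Vav1-Cre arrays (SD, n = 4 each), a difference of -0.14 log2 (SE 0.11), or -0.08 without Vav1-Cre replicate 3. Slamf1, which encodes CD150, measured 7.40 ± 0.47 against 6.68 ± 0.63, a difference of -0.73 (SE 0.32, adjusted p = 0.75), or -0.43 without Vav1-Cre replicate 3. Cd48 measured 6.26 ± 0.44 against 6.63 ± 0.56, a difference of 0.37 (SE 0.30), or 0.18 without Vav1-Cre replicate 3, 0.15 without f/f replicate 3 and 0.62 without Vav1-Cre replicate 4. Ly6a, which encodes Sca1, had no probe set assigned to it alone and was not analysed here.

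Transcripts of the sex chromosomes differed among the f/f arrays. Xist, the RNA that coats the inactive X chromosome, measured 11.22, 4.81, 10.27 and 10.48 log2 in f/f replicates 1 to 4 and 5.49, 5.76, 4.36 and 4.78 in Vav1-Cre replicates 1 to 4. The Y-linked gene Eif2s3y measured 3.46, 7.65, 7.37 and 7.53 in the f/f arrays and 7.24 to 7.78 in the Vav1-Cre arrays. High Xist without the Y-linked transcript was thus seen in 1 f/f array and both together in 2 f/f arrays, while the last f/f array and all 4 Vav1-Cre arrays had low Xist and a high Y-linked transcript. The Xist difference of -4.10 log2 (SE 1.20) did not pass over all genes (adjusted p = 0.73) and passed when adjusted over the list alone. Without f/f replicate 2 the Xist log2 difference was -5.56 with an adjusted p of 0.00422, and Xist was then the only gene called. With the Xist level as a covariate, a setting chosen after seeing the data, 8 lists passed, 5 of them among the 15, namely granulocyte, cell cycle, oxidative phosphorylation, ribosomal protein and olfactory receptors, and the stem cell identity list had a mean difference of -0.0046 log2 (adjusted p = 0.827). Among the f/f arrays only replicate 2 had low Xist, so all values with this covariate rest largely on that array against the Vav1-Cre arrays. Among the lists kept, oxidative phosphorylation was at 0.38 (0.24 without the covariate), ribosomal protein at 0.28 (0.11) and olfactory receptors at -0.12 (-0.04). The oxidative phosphorylation and ribosomal protein means of f/f replicate 2, 8.77 and 8.87 log2, lay below all Vav1-Cre arrays. Its olfactory receptor mean, 3.34, lay above them. That array also had the narrowest interquartile range of the 8, 2.93 log2, so these larger differences cannot be read as effects adjusted for sex. The lists gained were heat shock (0.27, adjusted p = 0.00353), ribosome biogenesis (0.14, adjusted p = 0.0124) and apoptosis (0.16, adjusted p = 0.0207). The granulocyte list then had a mean difference of 0.90 log2 instead of 1.94. Of the other lists that no longer passed, the mast cell list at 0.51 and replication histones at 0.28 moved little, while monocyte genes were at 0.19, erythroid at 0.20, B cell at 0.18, T and NK cell at 0.05, receptor segments at 0.35, megakaryocyte at -0.08 and chromatin genes at -0.06.

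**Figure D4:**
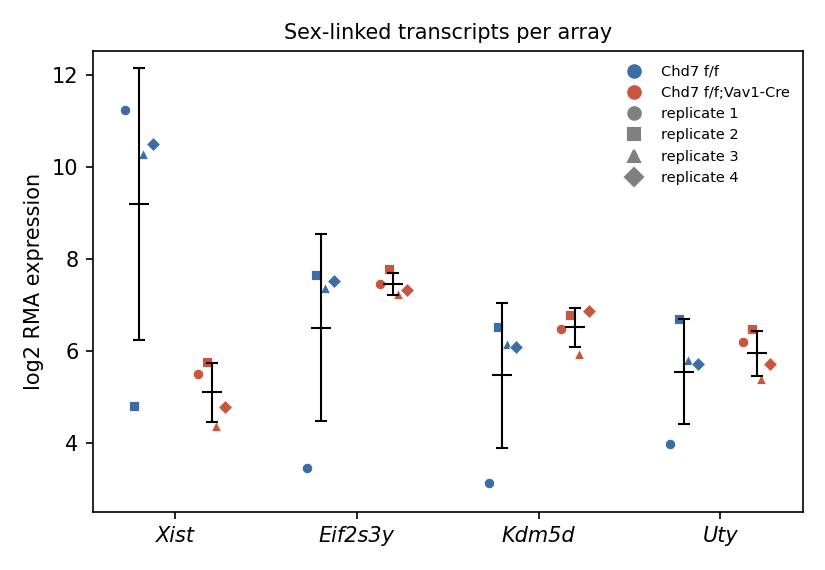
Log2 expression (y axis) of Xist and of 3 Y-linked genes (x axis) in each array, with f/f in blue, Vav1-Cre in red and the symbol giving the replicate, and black bars for the mean and SD of 4 arrays. Xist lies at 10.27 to 11.22 in 3 f/f arrays and at 4.36 to 5.76 in the other 5 arrays.

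In a principal component analysis of all 22180 genes the first component held 34.5% of the variance. The f/f arrays scored -27.6 to -6.96 on it and the Vav1-Cre arrays -3.83 to 59.8, without overlap (two-sided exact permutation p = 0.0286, the smallest possible). Vav1-Cre replicate 3 alone scored 59.8, and the next array scored 8.93. Camp and immunoglobulin kappa segments had the largest positive weights, and Xist, high in 3 of 4 f/f arrays, had the largest negative weight (-0.066). The second component held 16.7% and set f/f replicate 2, at -34.5, apart from f/f replicate 3, at 28.6.

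**Figure D5:**
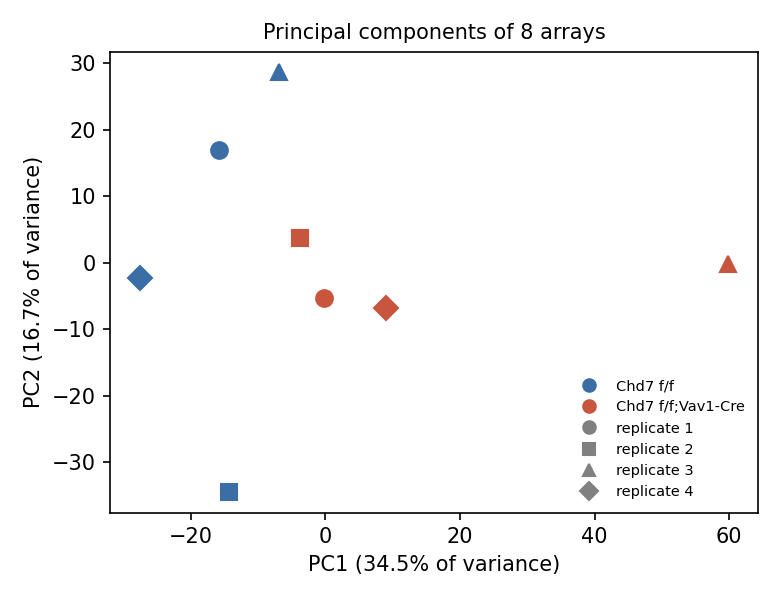
Scores of the 8 arrays on the first component (x axis, 34.5% of variance) and the second component (y axis, 16.7% of variance), with f/f in blue, Vav1-Cre in red and the symbol giving the replicate. Vav1-Cre replicate 3 lies at 59.8 on the first component, far from the other 7 arrays.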

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

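The tests of neutrophil carry-over, of Vav1-Cre replicate 3 and of the Chd7 background level were chosen only after the result was seen, and so were the covariates for the Xist level and the late neutrophil level.

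Among 138 groups of 4 arrays examined for named values and list means, 7 held an array far from the other 3, judged by its gap to the nearest array as a share of the whole range. Chance gives about 1 in 20, or 6.9 here, so the number of such arrays is what chance gives, although 4 of the 7 concern Vav1-Cre replicate 3. In that array the stem cell identity list was low (7.73 against 7.87 to 7.89 log2, gap share 0.885), the monocyte, macrophage and dendritic list was high (6.73 against 6.09 to 6.19, 0.849), the mast cell, basophil and eosinophil list was high (6.39 against 5.48 to 5.62, 0.855) and the cytokine receptor list was high (7.08 against 6.78 to 6.81, 0.896). In the f/f arrays, replicate 2 was high for CHARGE syndrome and neural crest genes (4.99 against 4.90 to 4.91, 0.896) and low for Xist (4.81 against 10.27 to 11.22, 0.851), and replicate 3 was high for replication histones (6.55 against 5.96 to 6.06, 0.839).

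The higher granulocyte genes of the Vav1-Cre arrays have both a technical and a biological reading. The 16 late neutrophil genes, such as Camp, Ngp and S100a8, varied together within the groups (mean correlation 0.821, against at most 0.355 for 1000 random lists), as a varying share of mature neutrophils in the sorted cells might give, although the sort removed Gr1- and Mac1-positive cells. The random lists were matched on expression level only. Their comparison therefore cannot tell carried-over neutrophils from a myeloid shift within the sorted cells. By group mean 15 of the 16 genes were above background in f/f arrays, but their level was 7.27 and 7.94 in f/f replicates 1 and 2 and 5.11 and 5.31 in replicates 3 and 4, where Camp, at 4.12 and 3.45, was below background. The 7 early granule genes, such as Mpo and Elane, differed by 1.07 ± 0.37 log2 (SE) and by 0.618 ± 0.605 with the late neutrophil level as a covariate, so a part from neutrophils and a part from progenitors cannot be told apart with 8 arrays. Vav1-Cre replicate 3 as the whole source is argued against by a list difference of 1.55 ± 0.57 (SE) without it, against 1.94 ± 0.62 with it. With the Xist level as a covariate the difference was 0.904 ± 0.798, so sex composition and genotype, correlated at -0.742, cannot be told apart. The list mean of f/f replicate 2, the 1 f/f array with low Xist, was 7.59, just below 7.61 in the lowest Vav1-Cre array. A myeloid shift caused by loss of Chd7 stays open. No array carried Vav1-Cre without the floxed allele, so the driver itself cannot be told apart from loss of Chd7.

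The stem cell identity list was lower and the cell cycle list higher in the Vav1-Cre arrays. For dilution of the stem cell RNA by neutrophils, the late neutrophil level was used as a covariate. The stem cell difference was -0.0643 ± 0.139 (SE) with it, against -0.22 ± 0.09 without it. These values overlap within their errors, so dilution cannot be told apart from no dilution. For the cell cycle list the same covariate gave 0.290 ± 0.112 against 0.230 ± 0.066, which argues against mature neutrophils as its source. The early granule level was not used as a covariate, so granulocyte progenitors as a source were not tested. With the Xist level as a covariate the stem cell difference was -0.0046 ± 0.0777. Among the f/f arrays only replicate 2 had low Xist, with a stem cell list mean of 7.84. The adjusted value thus rests largely on that array and cannot separate sex from another trait of it. The mix of sexes in the f/f RNA stays a candidate explanation for the lower stem cell list that these arrays cannot decide. With the same covariate the cell cycle difference was 0.162 ± 0.10. It cannot be told apart from one made by sex, since 3 of 4 f/f and none of the Vav1-Cre arrays had high Xist. An effect of Chd7 loss on both lists stays open as a hypothesis, and the design cannot tell it apart from an effect of the Vav1-Cre driver.

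Chd7 was not lower in the Vav1-Cre arrays. Its mean stood at the 36.5 percentile of all genes and at the 91.6 percentile of olfactory and vomeronasal receptors, below the background level, so a probe set without signal over background is a candidate explanation. A probe set that covers exons outside the deletion, or incomplete deletion, was not tested.

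The 8 arrays can be parted into groups of 4 in 35 ways, with mirror images counted once. For genes at an adjusted p under 0.05 the genotypes gave 0 (by limma, with 1453 at an unadjusted p under 0.05) and the highest other split gave 1; all 35 splits must give at least 0, so this count tests nothing. For genes at an unadjusted p under 0.05, 5 splits gave at least the 1453 of the genotypes, and the highest other gave 1763. For gene lists 6 splits gave at least 15, and the highest other gave 18. For Reactome pathways 11 splits gave at least 132, and the highest other gave 247. Chance is thus not excluded for the last 3 counts.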

How the results depend on the processing

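The covariates for the Xist level and the late neutrophil level were chosen only after the result was seen.

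Of 2778 differences of 157 named genes other than Chd7 under all alternatives but those 2 covariates, 2773 kept their direction and their side of the threshold. Most of these genes were named for a small p in the same data, and none passed in the main fit. This outcome was thus largely fixed in advance and is no evidence for any of the differences. Genes at an adjusted p under 0.05 numbered 0 by limma (1453 at an unadjusted p under 0.05) and 0 to 1 with an array left out, the 1 being Xist without f/f replicate 2. With an unadjusted p under 0.05 and a 1.5-fold difference there were 380, by construction of the looser threshold.

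Of the 35 lists, 15 passed, 13 to 16 did under filters, scalings, variance models, averaged probe sets and ranks, and 14 to 16 with an array left out. There were 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 0 by fry (5), 8 with the Xist level and 7 with the late neutrophil level as a covariate. Reactome pathways numbered 132, 31 to 158 with an array left out, and 0 with an estimated correlation (30 at an unadjusted p under 0.05). The lowest counts were 31 without f/f replicate 2 and 65 without f/f replicate 4.

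The Chd7 difference of -0.01 log2 was 0.013 with array weights, -0.074 to 0.064 with an array left out, 0.22 with the Xist level and 0.14 with the late neutrophil level. It had no value under the filters, which remove Chd7. The Runx1 log2 difference ranged from -0.22 to 0.011 (without f/f replicate 3), the Eif2s3y log2 difference from -0.065 (without f/f replicate 1) to 1.33 and the Uty log2 difference from -0.12 (without f/f replicate 1) to 0.79 with an array left out, where f/f replicate 1 is the array with low Y-linked values. The Rpl3 log2 difference was -0.014 with probe sets averaged.

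Olfactory and vomeronasal receptors averaged 0.0069 with genes above background and 0.025 with those above the median, where few of them are kept. With the Xist level the stem cell list averaged -0.0046, with camera upward, and ribosome biogenesis 0.14. With the late neutrophil level monocyte genes averaged -0.096, T and NK cell genes -0.075, ribosome biogenesis 0.16, NF-kB genes -0.24 (0.04 without it), chromatin genes 0.049 and receptor segments 0.063, the last with camera downward. The first component held 34.5% of variance, 48.3% with the 1000 most variable genes, and 24.0% (without Vav1-Cre replicate 3) to 39.7% (without f/f replicate 2) with an array left out. The cause was not tested.

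With the replicate block there were 0 genes (1849 at an unadjusted p under 0.05), 16 lists (multipotent progenitor genes gained, 0.24, adjusted p = 0.0487) and 136 pathways, and Chd7 differed by -0.0073. After the group mean of each gene was taken off, same-number arrays correlated at -0.0899 to 0.237 over genes above background. The labels state no pairing, so the numbers were not taken to pair the samples, although 3 of 4 f/f arrays correlated best with their own number. All rows of the table were not run for lists and pathways, which need gene names. Signal limits dim genes: 54.9% of genes were above background.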

Other observations

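The test of zinc finger genes was chosen only after Zfp266 and Zfp747 were seen among the lower genes, and its class includes them.

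Non-coding RNAs held some of the larger single differences, none of them past the test over all genes. Mir181b-2, a microRNA gene of lymphoid and stem cells, measured 7.13 ± 1.28 log2 (SD, n = 4) in f/f arrays and 4.79 ± 0.31 (SD, n = 4) in Vav1-Cre arrays, a difference of -2.34 (SE 0.53, adjusted p = 0.73). Mir30e differed by -0.79 (SE 0.18) and Mir1949 by 0.88 (SE 0.21). Snord89, a guide RNA of the nucleolus, differed by 1.16 (SE 0.36), opposite in sign to Snord88a at -1.59 (SE 0.25). Primary transcripts and mature forms are not separated by these probe sets.

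Some single genes of the cell surface had a small unadjusted p, although the stroma and endothelium list had 15 of 25 members higher and the adhesion and homing list 15 of 33, and neither list passed. Emcn, a sialomucin of stem cells and vessels, differed by -0.98 (SE 0.33), Itga6, a laminin receptor subunit, by -0.47 (SE 0.16) and Pecam1 by -0.36 (SE 0.13), while Selplg, the P-selectin ligand of myeloid cells, differed by 0.57 (SE 0.19). None passed over all genes, with adjusted p of 0.73 each.

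Zfp266 and Zfp747 headed the named lower genes, which led to the hypothesis that zinc finger genes are lower as a class. Of 336 genes with a Zfp symbol, 243 had a lower mean in Vav1-Cre arrays, with a median difference of -0.13 log2, and 31 were lower and 1 higher at an unadjusted p under 0.05. The class averaged 5.91 ± 0.05 (SD, n = 4) in f/f arrays and 5.74 ± 0.14 (SD, n = 4) in Vav1-Cre arrays, with a two-sided exact permutation p of 0.0571, so the hypothesis did not pass the test set for it. Camera, which was not part of that test and compares the class with all other genes, gave a p of 3.36e-07 at the preset correlation and 0.0408 with an estimated correlation. Without Vav1-Cre replicate 3 the mean difference was -0.10 instead of -0.17 (exact permutation p = 0.0857, smallest possible 0.0286).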
